A study of Homo sapiens with 8 samples.

How the data were processed

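Gene expression was measured on 8 Agilent single-colour arrays, each hybridised with Cy3-marked cRNA from a human colorectal cancer cell line. The lines were HCT116, DLD1 and the sublines named HCT/FR1 and DLD/FR1, and each was grown without drug or with FR901464, a bacterial natural product that binds the SF3b complex of the splicing machinery. The drug was given at 10 ng/ml for 24 h. Total RNA was isolated with TRIzol and 0.1 µg of it was labelled with a low-input kit, per the labels' protocols. The 8 arrays fall into 4 groups of 2, formed by subline status (parental or FR1) and drug, with 1 HCT array and 1 DLD array in each group. That the FR1 sublines belong to HCT116 and DLD1 was read from their names. The labels do not say how the sublines were made, and the series title speaks of SF3B1 mutations without saying which lines carry them. Each line and condition has 1 array, so the cell lines served as the replicates, and p-values measure the spread between these lines on 1 array each.

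The deposited scanner files give each spot's processed signal as an intensity, made by Agilent Feature Extraction 10.10.1.1, per the file headers (version 10.10 in the submitters' processing notes), with background subtraction and spatial detrending by that software and protocol GE1_1010_Sep10. A deposited table of the whole series holds 8 columns of intensity values, 1 per array. Set against the scanner values, each column was the processed signal times one factor per array, between 1.82 and 8.80, so the table is linear and its genes are not centred. How the authors chose the factors stays unknown. The column medians, untreated and then treated, were 105 and 104 for HCT116, 110 and 107 for HCT/FR1, 72.4 and 90.3 for DLD1, and 87.0 and 78.9 for DLD/FR1. No scaling between arrays had been applied to the processed signal. All 8 arrays were from 1 slide and 1 scan, so no slide or scan effect could be separated or fitted. No spot was saturated. Between 42.0% (HCT116 with drug) and 58.1% (HCT/FR1 untreated) of spots were well above background per the software's own call. The number of arrays limits the precision.

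Of 58717 spots that are not controls, outlier spots were left out unless a probe had no other and replicate spots were averaged on the log2 scale, giving 50599 probes. Probes were named through the RefSeq accession in the array design and a RefSeq gene table of assembly GRCh38.p14, without versions. This named 28174 probes of 20503 genes and left 22425 probes unnamed; 28167 of the 29181 NM and NR accessions matched. The array design is annotated on hg19, so no coordinates are given. Where a gene had several probes, the probe with the highest mean signal over the 8 arrays was used, and probes of genes named in the text that lay 2-fold or more apart in the comparison at hand are stated. Genes were tested if that probe was well above background on at least 2 of the 8 arrays, which left 15849 genes.

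Values were log2 of the processed signal minus the array's 75th percentile. They were fitted with limma 3.58.1 in R 4.3.3 (lmFit, eBayes) on all 8 arrays, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. For the drug effects in the parental lines and in the FR1 sublines, and for their difference, the fit held a term per cell line, which sets each treated array against the untreated array of its own line (2 residual degrees of freedom, 2.2 prior degrees of freedom). The spread of a gene was pooled over the 4 lines, so its parental effect and its subline effect have the same SE. For untreated sublines against untreated parental lines the fit held the 4 groups and a term for background, HCT or DLD (3 residual and 2.38 prior degrees of freedom). The replicate numbers pair arrays of one background: across genes, untreated HCT116 correlated at r = 0.966 with untreated HCT/FR1 and at 0.852 with untreated DLD1, and untreated DLD1 at 0.991 with untreated DLD/FR1. Within single lines, which have no replicate, only sizes and counts past a 2-fold change are given.

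Because the signal of the treated parental arrays fell, the fits and list tests were also run on a scale set by spike-in RNA. That scale uses the 7 Agilent E1A spike-in probes with a signal over 100 on every array. These probes read synthetic RNA that Agilent's kits add to the RNA sample at labelling. The scale therefore stands for signal per amount of total RNA labelled, not per cell, and how the spike-in RNA was added is not given in the sources used here. Values are relative to the 75th percentile unless a spike-in scale is named. Where a gene was well above background on no array of a group, a fold is given as a bound, "at least N-fold": the brighter group's mean against the higher of the dim probe's own signal and the lowest signal among probes well above background, per array.

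The 34 gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, which asks whether a list moves relative to the other genes, with Benjamini-Hochberg adjustment over the 34 lists. camera with an estimated correlation and fry were run beside it. With an estimated correlation camera works with the fit's 2 or 3 residual degrees of freedom, so it could hardly call a list in this design. A list that it did not call is therefore not shown to be unmoved. The design, the lists, the rule for the genes named here and most alternatives were fixed before the data were examined, and the alternatives added afterwards are named as such. The rule took the 10 highest and 10 lowest called genes with at least a 2-fold change of one sign in both backgrounds, ranked by the smaller change; for the difference of drug effects the 5 highest and 5 lowest called genes by the fitted difference; where none passed, 5 of each direction as not called; up to 4 members per list with the largest fitted change; and SF3B1, VEGFA, CDKN1B, CDKN1A, MCL1, ABCB1, CCNE1, CCND1 and MYC. Of the 5 highest for the difference 1 gene is not reported here. A pair of planned items changed: the files hold no mean signal column, so the normexp alternative used the median signal, and the reference table gives no exon numbers, so single-exon genes were taken from a fixed list of intronless genes.

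The tests were tried on simulated arrays in which 200 of the 15849 genes had known changes, in 3 runs. For the drug in parental lines, 1.33% of 2-fold, 40.7% of 4-fold, 82.7% of 8-fold and 96% of 16-fold changes were recovered. For the drug in FR1 sublines these shares were 0%, 26%, 79.3% and 90.7%, and for untreated sublines against parental lines 1.33%, 55.3%, 87.3% and 96%. Of about 46789 unchanged genes over the 3 runs, 30, 9 and 17 were called in the 3 comparisons. A shifted list was found in 3 of 3 runs and other lists in 0. The simulated noise was independent between genes, so the list result does not cover lists of correlated genes. The spread came from the drug fit in each comparison. For untreated sublines against parental lines, which had a fit of their own, the shares recovered hold for that spread only.

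Alternatives were scaling by the median, by quantile normalization or by the spike-ins, normexp background correction with an offset of 50, the series table, other filters on dim probes, the mean of a gene's probes, an intensity trend in eBayes, other blocks, and each cell line left out in turn. Other splits of the arrays and tests for single outlying arrays were left out because groups of 2 allow neither. Figures were drawn with matplotlib 3.10.9, and files were read with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3.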

Results

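The series measured gene expression in 4 human colorectal cancer cell lines, HCT116, DLD1 and their FR1 sublines HCT/FR1 and DLD/FR1. Each line was grown for 24 h without drug or with 10 ng/ml FR901464, which inhibits SF3B1, the largest subunit of the SF3b complex that recognises the branch point of introns. The 8 arrays form 4 groups of 2: parental untreated, parental treated, FR1 untreated and FR1 treated, each with 1 HCT and 1 DLD array. The series title names an SF3B1 inhibitor and SF3B1 mutations as what might alter expression, and the comparisons below ask what the drug altered in parental lines, what it altered in FR1 sublines, whether these effects differed, and how untreated sublines differed from their parental lines. Each value of n = 2 below is 2 cell lines with 1 array per condition. The SE of a drug effect uses a spread pooled over parental lines and FR1 sublines. It can understate the spread between the parental lines.

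The treated parental arrays were dimmer than the untreated ones. The 75th percentile of the signal of gene probes was 579 untreated and 86.8 treated in HCT116 and 746 and 249 in DLD1, while it was 594 and 575 in HCT/FR1 and 659 and 673 in DLD/FR1. On a log2 scale these changes were -2.74, -1.58, -0.05 and 0.03, and the spike-in probes changed by 0.09, 0.24, -0.09 and -0.01 on the same arrays. Spots well above background made up 56.6% and 42.0% of spots in HCT116 without and with drug, 57.1% and 54.8% in DLD1, 58.1% and 57.0% in HCT/FR1, and 57.2% and 55.8% in DLD/FR1. The direction of many genes in the parental lines depended on the scaling. The median log2 change over all 15849 genes tested was 0.34 in the fit on the 75th percentile, -0.54 with median scaling, -0.32 with quantile normalization and -1.98 on the spike-in scale. In the FR1 sublines these medians were 0.01, 0.08, 0.01 and 0.05, for the difference of the drug effects -0.34, 0.63, 0.33 and 2.02, and for untreated sublines against parental lines -0.04, -0.13, -0.02 and -0.07. Each gene and group below is to be read relative to these medians.

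**Figure D1:**
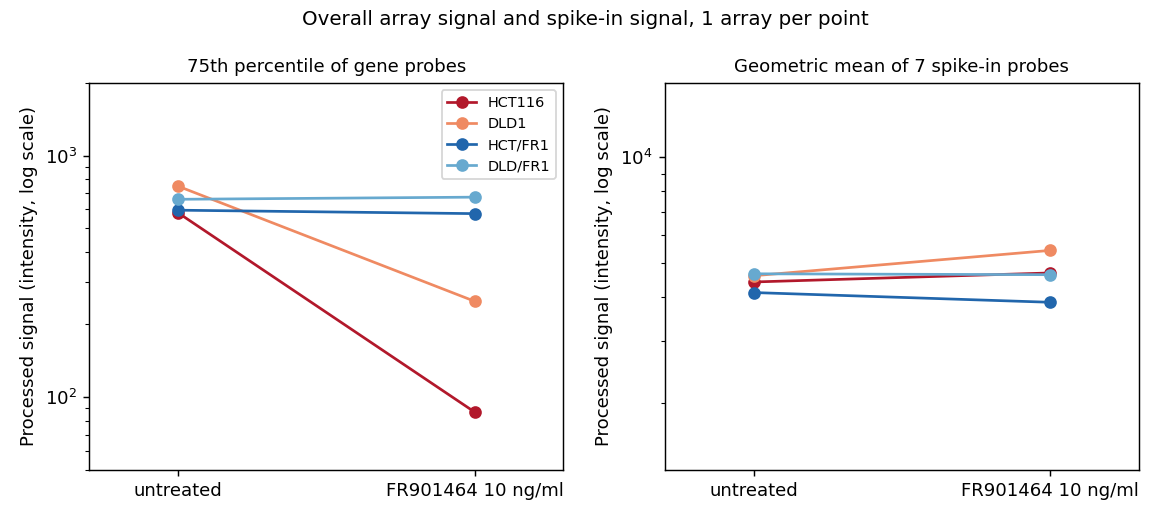
The 75th percentile of the signal of gene probes (left) and the geometric mean of the signal of 7 spike-in probes (right), without and with FR901464, on a log signal axis with 1 array per point. A drawn line joins the untreated and treated array of each cell line. On the left it falls for HCT116 (579 untreated, 86.8 treated) and DLD1 (746, 249) and is nearly level for the FR1 sublines. On the right it is nearly level for each of the 4 cell lines.

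Of the 10 genes that FR901464 raised most in both parental lines, 7 encode small nucleolar RNAs, which guide the chemical modification of ribosomal and spliceosomal RNA. SNORA68 rose by 7.45 ± 0.23 on the log2 scale (SE, n = 2 lines; 7.5 in HCT116 and 7.41 in DLD1; 5.13 on the spike-in scale). SNORA53 rose by 6.79 ± 0.37 (4.46), SNORD51 by 6.79 ± 0.44 (4.46), SNORA72 by 6.61 ± 0.41 (4.29), SNORD38B by 6.59 ± 0.32 (4.27) and SNORD100 by 6.39 ± 0.31 (4.07), with spike-in values in parentheses. SNORD119 rose at least 112-fold (at least 22.5-fold on the spike-in scale), from a level not well above background. The other 3 of the 10 highest genes were KRTAP3-1, a hair keratin-associated protein (7.5 ± 0.53; 5.18; 7.27 in HCT116 and 6.10 in DLD1 with a second probe), TMCO2 (at least 36.8-fold; 7.37-fold) and XCL1, a chemokine (at least 29.9-fold; 5.98-fold), the last 2 not well above background in untreated parental lines.

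The 10 lowest genes included WIPI1, a phosphoinositide-binding protein of autophagy, which was at least 28.3-fold lower with the drug (at least 142-fold on the spike-in scale; n = 2 lines), and CBX7, a chromobox protein of Polycomb complexes, at least 21.8-fold lower (109). A second CBX7 probe gave log2 changes of 2.82 in HCT116 and 2.61 in DLD1, so the CBX7 value holds for 1 of its probes. A second DZIP3 probe gave -3.37 and -3.81. SLC38A9, a lysosomal amino acid transporter, was at least 22.0-fold lower (110), DCP1B, an mRNA decapping factor, 21.6-fold (108), TMPO, a lamina-associated protein, 14.7-fold (73.3), DZIP3, a ubiquitin ligase, 12.3-fold (61.6), FBXO16 10.7-fold (53.6), IFT81, an intraflagellar transport protein, 10.3-fold (51.3) and PTER 8.04-fold (40.2), each as a lower bound. SLC7A2, a transporter of cationic amino acids, fell (-5.24 ± 0.26, and -7.57 on the spike-in scale) and was well above background on 1 of 2 treated arrays. Second probes of TMPO (-2.91 in HCT116, 0.43 in DLD1) and IFT81 (-0.69, -3.23) gave other values. The limma fit gave an adjusted p of 0.00845 for each of these 20 genes, and 0.00426 on the spike-in scale for the 10 lower ones.

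**Figure D2:**
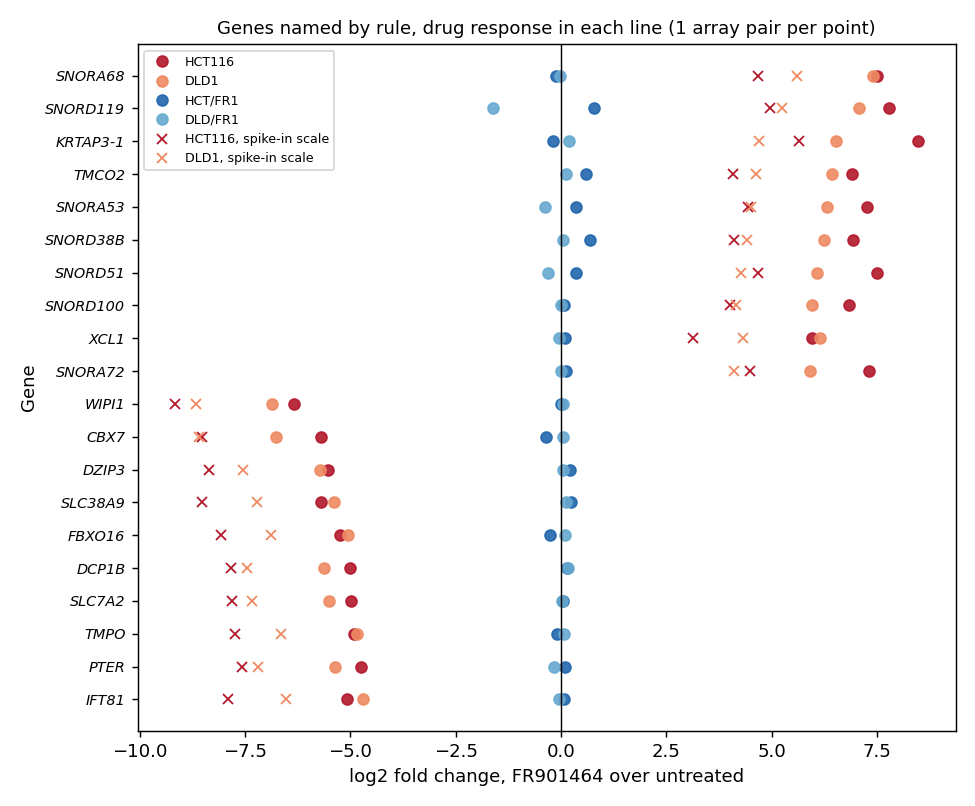
Log2 change with FR901464 of the 10 highest and 10 lowest genes, with 1 dot per cell line on the 75th percentile scale and crosses for HCT116 and DLD1 on the spike-in scale. Each of the 20 genes has one sign in HCT116 and DLD1 on both scales, as for SNORA68 (7.45 in the fit, 5.13 on the spike-in scale) and SLC7A2 (-5.24, -7.57), and the dots of the FR1 sublines lie near 0.

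Of 36 G2/M genes 26 fell, 0 rose and 10 did not pass (28 fell adjusted over the list alone). Their median was -2.35, and -4.67 on the spike-in scale (camera adjusted p = 6.44e-10, but adjusted p = 0.793 with an estimated correlation). Among those that fell were NDC80 of the outer kinetochore (-4.72 ± 0.95, SE, n = 2, and -7.04 on the spike-in scale), BUB1, a spindle checkpoint kinase (-4.31 ± 0.27, -6.63), HMMR (-4.08 ± 0.38, -6.40) and CCNA2, the cyclin of S phase and G2 (-3.54 ± 0.44, -5.87). Their limma adjusted p was 0.0212, 0.00845, 0.00856 and 0.0101. An estimated correlation leaves camera 2 residual degrees of freedom, so the lack of a call with it says little here or for the lists below. Of 42 genes of DNA replication and G1/S 23 fell, 1 rose and 18 did not pass, with equal counts adjusted over the list alone. Their median was -1.30, and -3.62 on the spike-in scale (camera adjusted p = 3.19e-07, but adjusted p = 0.793 with an estimated correlation). POLE2, a subunit of DNA polymerase epsilon (-5.05 ± 0.40, spike-in -7.37), RFC4 of the clamp loader (-4.04 ± 0.53, -6.36) and RRM2 of ribonucleotide reductase (-3.81 ± 0.25, -6.13) fell. Of 37 DNA repair genes 20 fell, 4 rose and 13 did not pass (21 and 5 adjusted over the list alone). Their median was -1.36, and -3.68 on the spike-in scale (camera adjusted p = 0.000244, but adjusted p = 0.793 with an estimated correlation). BRCA1 (-4.26 ± 0.48, spike-in -6.58) and FANCC (-4.0 ± 0.86, -6.32) fell, but another FANCC probe gave -2.52 in HCT116 and 1.58 in DLD1. The DNA repair list was not called on the spike-in scale (camera adjusted p = 0.058). NDC80, BUB1, CCNA2, POLE2, BRCA1 and FANCC were well above background on 1 of 2 treated arrays.

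A pair of further lists fell relative to other genes. Of 33 genes of cholesterol and fatty acid synthesis 11 fell, 3 rose and 19 did not pass (9 and 3 adjusted over the list alone). Their median was -0.44, and -2.76 on the spike-in scale (camera adjusted p = 0.00866, but adjusted p = 0.793 with an estimated correlation). FADS1, a fatty acid desaturase (-3.73 ± 0.31, spike-in -6.05), and SREBF1, which encodes SREBP-1 (-3.19 ± 0.64, -5.51), fell (n = 2). FADS1 was well above background on 1 of 2 treated arrays, and another SREBF1 probe gave 2.44 and 3.48. Of 22 genes reported as altered in splicing in SF3B1-mutant tumours 7 fell, 1 rose and 14 did not pass, with equal counts adjusted over the list alone. Their median was -0.72, and -3.04 on the spike-in scale (camera adjusted p = 0.0212, but adjusted p = 0.793 with an estimated correlation). ARMC9 fell (-3.25 ± 0.38, spike-in -5.57), with -2.15 in HCT116 and -2.09 in DLD1 for a second probe. DVL2, of Wnt signalling, had a value of -2.36 ± 0.70 that did not pass (adjusted p = 0.053) but passed as lower on the spike-in scale (-4.69, adjusted p = 0.0196). Neither list was called on the spike-in scale (camera adjusted p = 0.0757 and 0.0722).

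In the 8 lists that follow members rose on the 75th percentile, while the list medians lay below 0 on the spike-in scale. The counts of members that rose or fell hold for the 75th percentile alone unless a scale is named. Over all genes the split turned on the spike-in scale, with 304 called higher and 9822 lower. All 53 ribosomal protein genes rose on the 75th percentile, and 53 adjusted over the list alone. Their median was 1.78 against -0.54 on the spike-in scale and -0.02 with quantile normalization (camera adjusted p = 6.44e-10, and 0.594 with quantile normalization, but adjusted p = 0.793 with an estimated correlation). On the spike-in scale 3 of these genes were called lower and 0 higher. RPL41 (2.15 ± 0.35) and RPLP2 (2.11 ± 0.33) had the largest values, against -0.17 and -0.21 on the spike-in scale. Of 47 KRAB zinc finger genes, which encode DNA-binding repressors, 35 rose, 1 fell and 11 did not pass (37 and 1 adjusted over the list alone). Their median was 1.72 against -0.60 on the spike-in scale (camera adjusted p = 2.16e-06, but adjusted p = 0.793 with an estimated correlation). ZNF26 rose by 4.35 ± 0.45 (2.03 on the spike-in scale) and ZNF14 by 4.05 ± 0.36 (1.73). Of 37 intronless genes other than histones 17 rose, 3 fell and 17 did not pass, with equal counts adjusted over the list alone. Their median was 1.32 against -1.0 on the spike-in scale (camera adjusted p = 0.0254, but adjusted p = 0.793 with an estimated correlation). KTI12 rose by 4.69 ± 0.56 (2.37) and TSPYL4 by 4.68 ± 0.37 (2.36). The median of the intronless genes lay 0.976 above that of all other genes, and 0.993 above with quantile normalization. The list was called in 13 of 16 alternatives and lost its call with normexp (camera adjusted p = 0.187), among others.

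Of 34 immediate early genes 19 rose, 2 fell and 13 did not pass (22 and 2 adjusted over the list alone). Their median was 1.99 against -0.34 on the spike-in scale (camera adjusted p = 0.000627, but adjusted p = 0.793 with an estimated correlation). ATF3, a stress-induced transcription factor, rose by 5.34 ± 0.33 (3.02 on the spike-in scale), CCN1, a matricellular protein, by 5.09 ± 0.34 (2.77) and BHLHE40 by 4.50 ± 0.24 (2.18). Other ATF3 probes ranged from 4.31 to 5.61 in HCT116 and from 1.44 to 4.97 in DLD1, where the lowest was -0.38 on the spike-in scale. Of 18 snoRNA host and NMD-sensitive transcripts 11 rose, 2 fell and 5 did not pass (12 and 2 adjusted over the list alone). Their median was 1.43 against -0.89 on the spike-in scale (camera adjusted p = 0.0212, but adjusted p = 0.793 with an estimated correlation). SNHG15 rose by 4.96 ± 0.43 (2.64) and GADD45B by 4.34 ± 0.43 (2.02). This list was called in 11 of 16 alternatives, and not with quantile normalization or normexp (camera adjusted p = 0.128 and 0.26), among others. Of 9 blood cell markers 6 rose, 0 fell and 3 did not pass (9 rose adjusted over the list alone). Their median was 2.08 against -0.24 on the spike-in scale (camera adjusted p = 0.00731, but adjusted p = 0.793 with an estimated correlation). They included CD14 (3.98 ± 0.37, spike-in 1.65) and NKG7 (at least 4.97-fold, with no bound above 1 on the spike-in scale). By construction a probe of unchanged signal rises on the 75th percentile scale by as much as that percentile fell. The percentile changed by -2.74 in HCT116 and -1.58 in DLD1, and the marker medians were 2.39 and 1.51. For the list as a whole this rise is therefore not told apart from unchanged signal.

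Of 34 core spliceosome genes outside the U2 particle 17 rose, 1 fell and 16 did not pass, with equal counts adjusted over the list alone. Their median was 0.89 against -0.00195 with median scaling and -1.44 on the spike-in scale (camera adjusted p = 0.0212, and 0.185 with median scaling, 0.218 with quantile normalization, 0.532 with normexp and 0.892 on the spike-in scale, but adjusted p = 0.793 with an estimated correlation). PRPF38B rose by 3.21 ± 0.34 (0.88 on the spike-in scale) and SNRPD1 by 2.34 ± 0.31 (0.02). Of 33 genes of the mitochondrial respiratory chain 17 rose, 2 fell and 14 did not pass (19 and 3 adjusted over the list alone). Their median was 1.08 against -0.14 with quantile normalization and -1.24 on the spike-in scale (camera adjusted p = 0.0377, and 0.192 with median scaling, 0.686 with quantile normalization and 0.43 on the spike-in scale, but adjusted p = 0.88 with an estimated correlation). UQCRFS1 (2.22 ± 0.27) and NDUFB3 (2.18 ± 0.32) rose but were -0.10 and -0.14 on the spike-in scale.

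**Figure D3:**
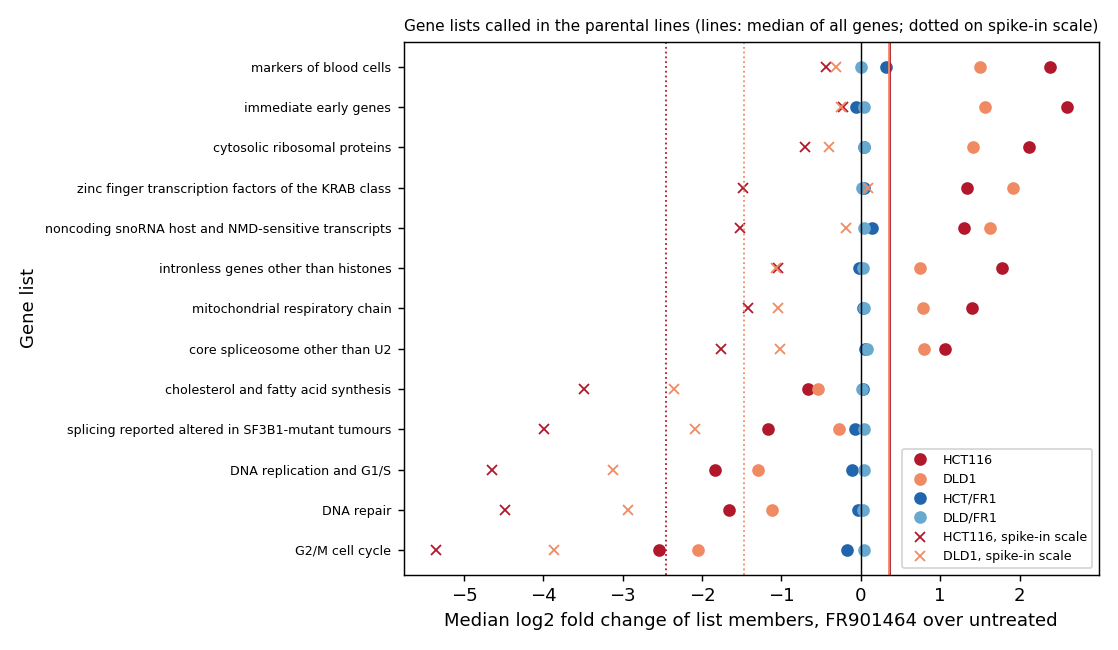
Median log2 change with FR901464 of the 13 lists called in the parental lines, with 1 dot per cell line on the 75th percentile scale, crosses for HCT116 and DLD1 on the spike-in scale, and vertical lines at the medians of all genes (dotted for spike-in). G2/M genes had a median of -2.35 in the fit and -4.67 on the spike-in scale, and ribosomal protein genes 1.78 in the fit, which turned to -0.54 on the spike-in scale.

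SF3B1, the drug's target, rose by 1.16 ± 0.25 (limma adjusted p = 0.0248) but was -1.16 on the spike-in scale (0.0844). VEGFA, an angiogenic factor, rose by 2.58 ± 0.49 (0.26 on the spike-in scale), CDKN1B, the CDK inhibitor p27, by 1.36 ± 0.24 (-0.96) and MCL1, an anti-apoptotic BCL2 relative, by 1.75 ± 0.31 (-0.57), with adjusted p of 0.0186, 0.0166 and 0.0163; another VEGFA probe gave -1.78 in HCT116 and 0.24 in DLD1. CDKN1A, the CDK inhibitor p21, did not pass (1.77 ± 0.56, adjusted p = 0.0609; -0.55 on the spike-in scale), nor did ABCB1, a drug efflux pump (-0.75 ± 0.40, 0.191; -3.07), CCNE1 (0.32 ± 0.33, 0.469; -2.01), CCND1 (0.36 ± 0.67, 0.685; -1.96) or MYC (0.78 ± 0.90, 0.506; -1.54). MYC was 2.55 in HCT116 and -0.99 in DLD1, and another ABCB1 probe gave 1.27 and -1.15. CDKN1A and ABCB1 were well above background on 1 of 2 treated arrays. ABCB1, CCNE1 and CCND1 passed as lower on the spike-in scale (adjusted p = 0.00446, 0.00674 and 0.0275).

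The other 21 lists were not called by camera on the 75th percentile. The test on the spike-in scale called 3 of them: p53 targets above other genes (median -0.75, adjusted p = 0.00157), the stress and unfolded protein response above them (-1.22, 0.00589) and histones below them (-2.76, 0.00277), but adjusted p = 0.973 with an estimated correlation for each of the 3. Values on the 75th percentile follow. Among them were differentiated colonic epithelium (25 genes, median 1.27, adjusted p = 0.0513), integrated stress and unfolded protein response (36, 1.1, 0.106), histones (53, -0.44, 0.108), SR proteins and their kinases (21, 0.95, 0.179), p53 targets (31, 1.57, 0.238), NF-kB targets (26, 0.80, 0.445) and the SF3a, SF3b and U2 genes (21, 0.27, 0.529). Adjusted p was 0.206 for epithelial-mesenchymal transition, 0.211 for fibroblast markers, 0.423 for Wnt targets, 0.676 for endothelial markers, 0.724 for elongation factors, ribosome biogenesis, interferon-stimulated genes and hnRNPs, and 0.766 for genes reported as sensitive to SF3B1 inhibitors. It was 0.839 for apoptosis regulators and nonsense-mediated decay factors, 0.923 for drug efflux genes, and 0.99 for heat shock and hypoxia genes. Members of these lists still moved, among them PPP1R15A, which recruits a phosphatase to eIF2α (4.11 ± 0.23; 1.79 on the spike-in scale), CXCL8, a chemokine (at least 5.62-fold; 1.13-fold), SF3B5 (3.24 ± 0.28; 0.91), SNRPA1 of the U2 particle (-3.18 ± 0.30; -5.50), PLK2 (3.51 ± 0.38; 1.19), SRSF8 (3.56 ± 0.43; 1.24) and H2BC7 (-3.02 ± 0.24; -5.34). SF3B4 (2.43 ± 0.27; 0.11) and PHF5A (2.40 ± 0.23; 0.08), of the SF3b complex, also rose.

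In the parental lines, limma called 7720 of 15849 genes, 4815 higher and 2905 lower, and 9131 had an unadjusted p under 0.05. This fit pools the spread with that of the FR1 sublines. The parental arrays fitted alone gave 5251 genes, 3147 higher and 2104 lower. Of the 4815 higher genes, 3932 were well above background on both treated parental arrays and 201 on neither. The split was 304 higher and 9822 lower on the spike-in scale, 1881 and 5286 with median scaling, 2339 and 3712 with quantile normalization, 6873 and 2975 with normexp, and 2469 and 4378 on the authors' deposited table. All 304 genes higher on the spike-in scale were also higher on the 75th percentile, and all 2905 genes lower on the 75th percentile were also lower on the spike-in scale, while 894 were higher on one and lower on the other. Of the lists, camera called 13, with 8 higher and 5 lower, 0 with an estimated correlation, and fry called 17. At the preset correlation, G2/M, DNA replication, KRAB zinc finger and immediate early genes were called in 16 of 16 alternatives. Ribosomal protein, DNA repair, cholesterol synthesis and blood cell genes were called in 15, SF3B1-mutant splicing in 14, the core spliceosome in 6 and the respiratory chain in 5. Without the line block the fit called 3163 genes. With HCT116 or DLD1 left out, the other parental line was set against the spread of the FR1 sublines alone. The counts of those fits are no measure of robustness and are not given.

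In the FR1 sublines no gene passed the test. SF3B1 was 0.14 ± 0.25, VEGFA 0.00 ± 0.49, MCL1 -0.08 ± 0.31 and MYC -0.17 ± 0.90 (log2 ± SE, n = 2 sublines), with values of 0.03, 0.06, -0.01 and 0.05 for CDKN1B, CDKN1A, CCNE1 and CCND1. The SE and the test use a spread pooled over all 4 lines, parental lines included, not the spread between the sublines alone. VEGFA, for example, was -0.08 in HCT/FR1 and 0.08 in DLD/FR1. The limma fit called none (0 called, 108 with an unadjusted p under 0.05, lowest adjusted p 1.0). It called 0 on the spike-in scale, with 83 at an unadjusted p under 0.05, and 0 with the FR1 arrays fitted alone, with 798. The largest changes that were alike in both sublines did not pass: SNORD114-21, at least 4.98-fold higher, TNFRSF4, a T cell co-stimulatory receptor (1.44 ± 0.30), PROSER2-AS1 (at least 1.28-fold), JAM2 (1.35 ± 0.35, well above background on 1 of 2 arrays in each group) and NAT16 (at least 1.68-fold). On the lower side stood LINC02226 (at least 1.89-fold), DHH, a hedgehog ligand (at least 1.26-fold), and HEXA-AS1 (at least 1.26-fold). OR5J2 and STMN2, also in this group, were not well above background with or without drug, so no fold is given. The 53 histone genes were the 1 list called. Their median was -0.10, with 0 genes passing over all genes and 0 adjusted over the list alone (camera adjusted p = 0.0401, but adjusted p = 0.968 with an estimated correlation). The list was not called with median scaling (0.059), on the spike-in scale (0.051) or with no filter on dim probes (0.526), and was called in 11 of 16 alternatives. In simulated arrays this fit recovered 0% of 2-fold and 26% of 4-fold changes, so most changes of that size would not have passed.

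In single lines, 8906 genes changed 2-fold or more in HCT116 (4737 higher, 4169 lower) and 8095 in DLD1 (4688, 3407), against 171 in HCT/FR1 (70, 101) and 244 in DLD/FR1 (54, 190), with no test since each line has 1 array per condition. On the spike-in scale these counts were 12252 (412, 11840), 10061 (550, 9511), 176 and 238. Log2 changes correlated across genes at r = 0.684 between HCT116 and DLD1 and at 0.143 between the sublines, and from -0.112 to 0.0383 between a parental line and a subline; genes are not independent replicates. Over the 7720 genes called in parental lines, the slope of subline on parental changes was -0.00613, with median sizes of 0.0860 and 1.85. With genes taken 2-fold in one background and measured in the other it was -0.0237 and 0.00676.

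The difference of the drug effects was tested directly. WIPI1 (6.60 ± 0.37), CBX7 (6.07 ± 0.51, first probe), DZIP3 (5.75 ± 0.33) and SLC38A9 (5.73 ± 0.34) had higher drug effects in the sublines than in the parental lines (fitted log2 difference ± SE). SNORD119 (-7.85 ± 0.92), SNORA68 (-7.53 ± 0.32), KRTAP3-1 (-7.50 ± 0.75), MEP1B, a metalloprotease (-7.43 ± 0.83), and FAM124B (-7.28 ± 0.68) had lower ones (limma adjusted p of 0.0317 for each). On the spike-in scale these differences were 8.97, 8.44, 8.11, 8.09, -5.48, -5.16, -5.14, -5.06 and -4.92. Sizes and rank are not measured for WIPI1, CBX7, DZIP3 and SLC38A9, not well above background in treated parental lines, and for SNORD119, MEP1B and FAM124B, not well above it in untreated parental lines or in the sublines. G2/M genes had a median difference of 2.23 (14 higher, 0 lower; 20 and 0 adjusted over the list alone; camera adjusted p = 1.06e-09, but adjusted p = 0.837 with an estimated correlation) and DNA replication genes 1.31 (11 and 0; 15 and 0 adjusted over the list alone; 5.72e-07, but adjusted p = 0.837 with an estimated correlation, as for each list that follows). These 2 medians were 4.59 and 3.67 on the spike-in scale. DNA repair genes had a median of 1.3 (10 higher, 1 lower; 14 and 1 adjusted over the list alone; camera adjusted p = 0.000277), cholesterol and fatty acid synthesis 0.52 (5 and 1; 4 and 1; 0.0109) and the SF3B1-mutant splicing list 0.68 (2 and 0; 0 and 0; 0.0274), against 3.66, 2.88 and 3.04 on the spike-in scale. Ribosomal protein genes lay at -1.72 (0 higher, 22 lower; 0 and 52 adjusted over the list alone; camera adjusted p = 1.06e-09), against 0.65 on the spike-in scale and 0.07 with quantile normalization (0.775). KRAB zinc finger genes lay at -1.73 (0 and 17; 1 and 30; 1.76e-06), immediate early genes at -2.06 (1 and 13; 2 and 14; 0.000518) and blood cell markers at -1.87 (0 and 4; 0 and 6; 0.0109), against 0.63, 0.30 and 0.50 on the spike-in scale. Intronless genes lay at -1.19 (1 and 10; 2 and 14; 0.0274), snoRNA host transcripts at -1.30 (0 and 7; 0 and 7; 0.0305) and the core spliceosome at -0.80 (0 and 5; 0 and 0; 0.0384), against 1.17, 1.07 and 1.56 on the spike-in scale, and 0.16 for the core spliceosome with median scaling.

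On the spike-in scale camera no longer called ribosomal protein genes, cholesterol and fatty acid synthesis or the SF3B1-mutant splicing list for the difference (adjusted p = 0.0688 for each), nor the core spliceosome (0.822, on the higher side). It called histones above other genes (median 2.81, 0.00782) and p53 targets (0.92, 0.0203) and the stress and unfolded protein response (1.38, 0.0224) below them, which the 75th percentile did not, but adjusted p = 0.96 with an estimated correlation for each of the 3. Of 15 alternatives at the preset correlation the core spliceosome was called in 4, snoRNA hosts in 10 and SF3B1-mutant splicing in 12. Ribosomal protein genes, blood cell markers and intronless genes were called in 13, cholesterol synthesis in 14, and the other 5 lists in 15.

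For the difference limma called 3443 genes, 1340 higher and 2103 lower in sublines (7032 with an unadjusted p under 0.05, lowest adjusted p 0.0317), and camera called 12 lists (0 with an estimated correlation, lowest adjusted p = 0.837; fry called 11). The split was 3116 higher and 654 lower with median scaling, and 6757 and 168 on the spike-in scale, and quantile normalization gave 1936 genes in all. The fit without a line block called 0 genes (3750 with an unadjusted p under 0.05). With any line left out, a lone line was set against the spread of the other lines. The counts of those fits moved widely and are not given.

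Untreated sublines against untreated parental lines showed higher medians for interferon-stimulated genes and differentiated colonic epithelium. The 36 interferon-stimulated genes had a median of 0.78 (1.45 in HCT, 0.22 in DLD; 0 genes passing over all genes and 1 adjusted over the list alone; camera adjusted p = 1.18e-10, but adjusted p = 0.371 with an estimated correlation), among them SAMD9L, an interferon-induced antiviral factor (at least 3.31-fold), OAS1 (2.31 ± 0.88) and IFIT1 (1.26 ± 0.40). The 25 epithelial genes had a median of 0.92 (1.78 in HCT, 0.07 in DLD; 0 genes passing; camera adjusted p = 2.88e-06, but adjusted p = 0.371 with an estimated correlation), with PHGR1 at 5.49 ± 3.67 (10.95 in HCT, 0.04 in DLD), TFF2, a trefoil peptide of mucus, at 3.81 ± 3.09 (8.98, -1.36), MUC13 at 3.63 ± 1.37 (6.32, 0.94) and CEACAM1 at 3.23 ± 1.36 (5.53, 0.92). The epithelial list was called in 14 of 16 alternatives, and not without HCT116 (camera adjusted p = 0.16) or without HCT/FR1 (0.677), while the interferon list was called in 16. None of these genes passed. OAS1, MUC13, MELTF, CALHM3 and PADI2 were well above background on 1 of 2 parental arrays, and GASK1A on 1 of 2 subline arrays. Other genes with the largest values that were alike in both backgrounds were KRT16P2 (at least 4.50-fold higher), MELTF (2.85 ± 0.34), CALHM3 (2.55 ± 0.46) and PADI2, a peptidylarginine deiminase (3.10 ± 0.98), and lower ANKRD26P1 (at least 2.81-fold), BIRC7 (at least 1.95-fold), GASK1A (-1.84 ± 0.50) and TMEM161B-DT (-1.57 ± 1.04). GARIN2, also lower, has no bound above 1. Second probes gave other values for SAMD9L (2.62 in HCT, -1.18 in DLD), MELTF (1.99, -0.80), PADI2 (2.89, 0.28), CEACAM1 (5.44, 0.43) and ANKRD26P1 (0.77, 0.57).

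The growth and splicing lists had medians below 0 in untreated sublines with 0 members passing in any, over all genes or adjusted over the list alone. These medians were -0.40 for cholesterol and fatty acid synthesis (camera adjusted p = 3.53e-07), -0.40 for ribosome biogenesis (6.1e-07), -0.26 for ribosomal proteins (1.6e-05), -0.27 for DNA replication (3.68e-05), -0.30 for G2/M (3.68e-05), -0.26 for the respiratory chain (4.05e-05), -0.30 for histones (0.00015), -0.25 for the core spliceosome (0.000366) and -0.24 for DNA repair (0.0017). Further medians were -0.29 for SF3B1-mutant splicing (0.00636), -0.17 for hnRNPs (0.00636), -0.19 for SF3a, SF3b and U2 genes (0.0092), -0.20 for nonsense-mediated decay factors (0.027), -0.17 for SR proteins (0.0455) and -0.34 for snoRNA hosts (0.0465). Each of these lists lay further below 0 in HCT than in DLD. The medians in HCT and DLD were -0.61 and -0.04 for snoRNA hosts, -0.65 and -0.18 for ribosome biogenesis, and -0.41 and -0.10 for ribosomal proteins. They were closer for DNA replication (-0.28 and -0.24) and SR proteins (-0.21 and -0.18). Of 16 alternatives, nonsense-mediated decay factors were called in 10, snoRNA hosts in 11, SF3B1-mutant splicing and hnRNPs in 12, SF3a, SF3b and U2 genes in 13, and the other lists but SR proteins in 14 or 15. SR proteins were called in 6 of 16 and not on the spike-in scale (median -0.20, camera adjusted p = 0.19), where the other 14 lists stayed called and fibroblast markers were called higher (0.45, 0.0262, but adjusted p = 0.751 with an estimated correlation). With quantile normalization 5 of these lists were not called: SR proteins (0.237), snoRNA hosts (0.232), nonsense-mediated decay factors (0.0914), SF3a, SF3b and U2 genes (0.0902) and hnRNPs (0.063). No list was called with an estimated correlation, where the lowest adjusted p was 0.371, or by fry (adjusted p = 0.5). The fixed genes did not pass: SF3B1 was -0.14 ± 0.26, ABCB1 -0.55 ± 0.71, CDKN1A 0.68 ± 0.77, MYC -0.89 ± 1.32, VEGFA -0.13 ± 0.48, CDKN1B 0.08 ± 0.38, MCL1 -0.13 ± 0.34, CCNE1 -0.05 ± 0.39 and CCND1 0.43 ± 0.64. In this comparison limma called 0 genes (332 with an unadjusted p under 0.05), 0 on the spike-in scale (173) and 0 on the untreated arrays alone (799). With DLD1, DLD/FR1 or HCT/FR1 left out the count was no longer 0, but a lone line was then set against the spread of the other lines. Of 76 genes bright in both untreated HCT lines and not well above background in untreated DLD1 or treated DLD/FR1, 5 were well above it on the untreated DLD/FR1 array. The median log2 of these 76 genes on that array was 0.0437 over the treated DLD/FR1 array and 0.26 over untreated DLD1. Without the untreated DLD/FR1 array limma called 0 genes and camera 13 lists.

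The untreated difference and the drug effect were compared across backgrounds. The FR1 minus parental difference in HCT correlated with the drug effect in DLD1, and the DLD difference with the drug effect in HCT116, at r = -0.0199 and 0.0952 across genes. Within a background, where both share the untreated parental array, r was 0.0409 for HCT and 0.176 for DLD, with covariances of 0.0667 and 0.132. Simulated unchanged arrays that shared a control gave r = 0.502 and a covariance of 0.0615. Their equal spread fixed that r in advance, and the real differences had wider and unequal spreads. The simulated r is therefore no measure for the observed ones. The untreated differences of HCT and DLD correlated at 0.169 across genes.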

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

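The tests of weak hybridisation, of an equal loss, of a faulty array and of a swapped array were chosen only after the result was seen.

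The drug effect differed between sublines and parental lines by limma's interaction test in 3443 genes. Ordered by the fit, the log2 differences of the subline effect from the parental effect were 6.60 for WIPI1, 6.07 for CBX7, 5.75 for DZIP3 and 5.73 for SLC38A9. On the lower side they were -7.85 for SNORD119, -7.53 for SNORA68, -7.5 for KRTAP3-1, -7.43 for MEP1B and -7.28 for FAM124B, but 7 of these 9 genes (all but SNORA68 and KRTAP3-1) were dim in at least 1 group, so their fitted sizes and their rank are not measured. In 176 genes HCT116 and DLD1 changed 2-fold or more in opposite directions on the 75th percentile and in 112 on the spike-in scale, 20 of them on both, and these differences were not tested. Among probes with no gene name, which the comparisons above leave out, 166 of 9019 were called higher and 2656 lower on the spike-in scale with the drug in parental lines. Of named probes 371 of 21337 were higher there, or 1.74% against 1.84% of unnamed ones, and on the 75th percentile 5495 unnamed probes were higher and 369 lower, or 60.9% higher against 29.8% of named ones.

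The treated parental arrays lost signal, with a 75th percentile change of -2.74 in HCT116 and -1.58 in DLD1. Spike-in probes rose slightly in place of falling, by -0.0312 of that change in HCT116 and by 0.24 on the log2 scale in DLD1, which argues against weak hybridisation, washing or scanning. The summed signal on the spike-in scale was 0.504 and 0.586 of the untreated arrays', which argues against a few genes merely taking up the RNA, although the share of the 100 brightest probes was 31.0% against 20.7% in HCT116. Changes of single genes spread at least 4.40 times as widely as in the sublines, which argues against an equal loss of all messages as the whole change. A loss common to all messages would leave this spread as it is, so the test cannot exclude one beneath changes of single genes. A loss of many messages per amount of total RNA may remain as a hypothesis, and RNA quality and RNA per cell were not measured in the data used here.

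Of 223 snoRNA genes tested, 182 rose and 0 fell on the 75th percentile, against 75 and 27 on the spike-in scale, and 0 were called in the sublines. Their median was at least 1.70 above that of genes matched on untreated signal, which argues against scaling as the source of that gap. On the spike-in scale their median was 0.59 in HCT116 and 0.25 in DLD1, against -2.60 and -1.45 for the matched genes. For the set as a whole, much of the rise on the 75th percentile is therefore not told apart from a fall of other genes. Whether snoRNA probes read unspliced host transcripts cannot be told apart from mature snoRNAs, since the difference of 0.290 between snoRNAs inside and outside other genes rests on 4 genes outside (permutation p = 0.658 and 0.740). For 644 other genes inside longer genes the excess was 0.756 (SE 0.112) in HCT116 and 0.353 (SE 0.0749) in DLD1, above 0 in both. In DLD1 it was under the 0.5 set for a general effect of nested position, although the strand of the genes was not used. A smaller effect of nested position is therefore not excluded. Host transcripts that kept their introns may still be a candidate source for the snoRNA probes, and a change in mature snoRNAs stays open too.

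Untreated HCT/FR1 lay over 8-fold from HCT116 in 204 genes (170 higher, 34 lower), against 25 in the DLD background, with 1 gene shared against 0.174 by chance. On the treated HCT/FR1 array 0.961 of these genes lay over 4-fold in the same direction, which argues against a fault of the single untreated HCT/FR1 array. Both HCT/FR1 arrays were set against the same untreated HCT116 array, so a fault of that array is not excluded. Of 86 genes bright in both DLD lines and dim in HCT116, 0.349 were raised 2-fold in HCT/FR1, which argues against admixed DLD cells as the source of the whole difference. The share raised without admixture was not measured, and a trace of DLD RNA is not excluded. The array correlated with HCT116 by 0.118 more than with any DLD array, which argues against a swap with one of these. How the subline was derived, its passage history and another HCT culture stay open and may account for the difference.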

How the results depend on the processing

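The tests on the parental or FR1 arrays alone, with the stricter rule for the brighter group without the single DLD/FR1 untreated array and with an estimated correlation on the spike-in scale were chosen only after the result was seen, as were those of lists and named genes with the background block, without a block or on the untreated arrays alone, whose gene counts were planned, and so was the 0.1 shift beyond which a correlation or slope counts as changed. Of the alternative values of named genes, 1797 kept direction and side of the threshold, 47 passed newly, 52 no longer passed and 54 changed sign, and of those of counts and correlations 144 stayed within their bound and 46 did not. Signal over background limits genes dim in a group to bounds. Slide and scan could not be run as a block because all arrays share 1 of each. Where no cause is named, the cause was not tested.

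For the drug in parental lines the replicate block by cell line mattered: without it 3163 genes were called in place of 7720, and for the difference of drug effects 0 in place of 3443. With no replicate block 0 lists were called in the FR1 sublines in place of 1, and SF3B1, CDKN1B, CCNA2, FANCC, FADS1, ATF3, CD14, NKG7, PLK2 and TNFAIP2 no longer passed in parental lines, nor did any of the 9 genes named for the difference. Without it histones were also called in parental lines and NF-kB targets in untreated sublines, where SR proteins were no longer called. With the background block as replicate block the core spliceosome was no longer called for the difference. The replicate block changed no other list call. Leaving out each line in turn gave 5251 to 12588 genes for the drug in parental lines, 242 to 11851 for the difference, 0 to 3 in FR1 sublines and 0 to 1770 for untreated sublines against parental lines. It gave 0 to 4 lists in FR1 sublines and 9 to 16 for untreated sublines. A lone line is then assumed to vary like the others.

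For the difference, quantile normalization called 1936 genes and 7 lists, the spike-in scale 6925 genes and normexp 7223. Lists called in FR1 sublines numbered 0 with median scaling, 4 with quantile normalization, 0 on the spike-in scale, 9 with normexp, 0 with no filter on dim probes, 3 on the FR1 arrays alone and 0 by fry. With an estimated correlation 0 lists were called in each of the 4 comparisons, on the 75th percentile and with spike-in scaling, and fry called 0 for untreated sublines. The estimated correlation left camera 2 or 3 residual degrees of freedom, and so little room to call a list. Past other thresholds, which by construction change the count, HCT/FR1 had 767 genes at 1.5-fold and 54 at 3-fold, DLD/FR1 593 and 130, and DLD1 4639 at 3-fold. With normexp HCT/FR1 had 10 and DLD/FR1 36.

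Median and spike-in scaling and the series table, which holds 1 factor per array, by construction shift all genes of an array alike, and for the other settings the cause was not tested. With the drug in parental lines, median scaling gave CCNE1 -0.57, CCND1 -0.53 and MYC -0.11, quantile normalization -0.41, -0.30 and -0.14, normexp -0.12 for CCNE1 and -0.0586 for CCND1, and the series table -0.42 and -0.38. The spike-in scale gave SF3B1 -1.16, CDKN1B -0.96, CDKN1A -0.55, MCL1 -0.57, CCNE1 -2.01, CCND1 -1.96, MYC -1.54, RPL41 -0.17, RPLP2 -0.21, UQCRFS1 -0.10 and NDUFB3 -0.14. In FR1 sublines CCNE1 was 0.0697 with median scaling and 0.0353 on the spike-in scale, and VEGFA -0.0181 with normexp, -0.0156 with the series table and -0.0205 with the mean of its probes. For untreated sublines CDKN1B was -0.0110 with median scaling and CCNE1 0.0520 with quantile normalization and 0.0262 with the series table. CBX7 was 2.72 in parental lines and -2.70 for the difference when probes had to be well above background on all 8 arrays, which by construction selects its other probe.

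With a line left out, CCNE1 ranged from -0.17 to 0.80, CCND1 from -0.94 to 1.65 and MYC from -0.99 to 2.55 in parental lines. In FR1 sublines MCL1 ranged from -0.18 to 0.0141, CCNE1 from -0.13 to 0.11, MYC from -0.36 to 0.0106 and VEGFA from -0.0769 to 0.0826. For untreated sublines TFF2 ranged from -1.35 to 8.98, PHGR1 from -0.45 to 11.4, ABCB1 from -1.45 to 0.34, VEGFA from -0.44 to 0.17, CDKN1B from -0.39 to 0.55, CCNE1 from -0.34 to 0.24, MYC from -2.52 to 0.75, CDKN1A from -0.28 to 1.64 and MCL1 from -0.42 to 0.17.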

Other observations

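All tests in this part were chosen only after the result was seen, since it reports nothing planned. Target genes of p53, which arrests growth after damage, had a median log2 change with FR901464 of 2.56 in HCT116 and 0.00471 in DLD1 (31 genes, 1 array per condition, no test). On the spike-in scale these medians were -0.27 and -1.82. Of 10000 random lists of equal size matched on mean signal 0 had a median difference between the lines as high as that of the p53 list, 1.96. The same held for immediate early genes (2.60 and 1.57, 0 of 10000) and for intronless genes (1.78 and 0.75, 0 of 10000), relative to other genes, although their spike-in medians were alike in both lines (-0.22 and -0.25, -1.04 and -1.07), while Wnt targets were at 1.59 and -0.81 (17 of 10000 as high). SR proteins and their kinases, at 0.55 in HCT116 and 1.3 in DLD1, and stress response genes, at 0.48 and 1.36, lay the other way (4 and 21 of 10000 as low), as did DNA replication (26), G2/M (41) and cholesterol synthesis (81). Genes reported as sensitive to SF3B1 inhibitors lay higher in HCT116 (70 of 10000 as high), and no further list had under 100 on either side. These values describe single arrays, and 34 lists were looked at.

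Probes of one gene often moved apart with the drug in parental lines. Among 2318 genes with several probes well above background on all arrays, probes lay 2-fold or more apart in 846 genes (36.5%) in HCT116 and 652 (28.1%) in DLD1, against 11 (0.475%) in each subline. In 160 genes they lay 4-fold or more apart in both parental lines and under 2-fold in both sublines, and in 150 of these the same probe was highest and the same probe lowest in both. The ranges in HCT116 and DLD1 were 6.33 and 6.06 on the log2 scale for SETDB1, a histone methyltransferase, 6.86 and 5.44 for SREBF1, and 6.35 and 5.07 for MKRN1. Gene values in this comparison therefore depend on the probe, and the part of the transcript each probe reads was not used here.

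In the untreated HCT/FR1 subline genes far from HCT116 and well above background on both untreated HCT arrays were PHGR1 (10.95 on the log2 scale), TSPAN8 (8.98), TFF2 (8.98) and PSCA (8.12) on the higher side and RNF43, a Wnt pathway inhibitor (-7.11), on the lower side. The treated HCT/FR1 array gave 11.16, 8.97, 8.59, 8.33 and -6.75 against the same HCT116 array. In the DLD background the values were 0.04, -0.31, -1.36, 1.23 and -0.40.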
